A study of Homo sapiens with 20 samples.

How the data were processed

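The data come from a transcriptome-wide assay of N1-methyladenosine (m1A), a methyl group on the Watson-Crick face of adenosine, in HEK293T cells, a human embryonic kidney line that expresses the SV40 large T antigen. Per the labels' protocols, RNA was bound to an anti-m1A antibody on protein G beads, and a sample taken before this immunoprecipitation (IP) served as input. An adapter was ligated to the 3′ ends of the RNA, the RNA was reverse transcribed with SuperScript-III or TGIRT-III, and a second adapter was ligated to the 3′ ends of the cDNA. The cDNA end, and so the 5′ end of the sequenced fragment, lies where reverse transcription ended. In some IP libraries the RNA went through a Dimroth rearrangement, an alkaline step that turns m1A into N6-methyladenosine, which does not block the enzymes. For overexpression, plasmids encoding TRMT6 and TRMT61A, the subunits of the nuclear tRNA m1A methyltransferase, were transfected under a CMV promoter and the cells were harvested 48 hours later.

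The authors deposited 1 file per strand and library that holds raw counts of read ends per base, and the unit was taken from the values of the deposited files: whole numbers, nearly all intervals 1 base wide, totals that differ between libraries, and counts on tRNA sequences that lie at the 5′ end. STAR, bedtools and the build hg19 are named in the submitters' processing notes; versions, parameters, removal of duplicate reads and the treatment of reads with several matching places are not given in the sources used here. Besides the hg19 chromosomes, the files carry separate sequences for 28S, 18S and 5.8S rRNA, 8 snRNAs and 31 tRNAs. A few further names that look like synthetic sequences entered no test. Some positions carry the counts of another position, so reads with several matching places may count at each. Nuclear copies of mitochondrial RNA are an example. No molecular identifiers are named in the labels, so PCR copies may be counted more than once and counting limits cover counting error only.

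The 20 libraries form 10 groups of 2: input, IP and Dimroth-treated IP with each enzyme in untransfected cells, and input and IP with TGIRT in overexpressing and in control cells. Groups and replicate numbers were taken from the sample titles. The titles of the libraries called control IP here also carry the word input, and their treatment label reads m1A IP; they are written as the libraries labelled control IP throughout. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. The 2 libraries of each group differed by more than sampling noise in every group, with a chi-square statistic per degree of freedom from 2.09 to 159 over windows, and each counted as 1 replicate. For a single value in 2 against 2 libraries, an exact two-sided permutation test cannot give a p below 0.333, so shares of read ends are given as mean ± SD without a test.

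Read ends were summed in strand-specific windows of 100 nt along every sequence. Windows with a mean of at least 5 read ends over the 20 libraries, 204428 in all, were tested with edgeR's quasi-likelihood test on the counts, with TMM scaling, 10 group means fitted to all 20 libraries (residual degrees of freedom 10, common dispersion 0.0517) and Benjamini-Hochberg adjustment at 0.05. The plan fixed before the data were examined named limma on coverage for this step and edgeR on window counts in case the files held read ends, and the latter applied. Levels (CPM) are edgeR's scaled counts on TMM-scaled library totals. A fold against a group without a read end is a bound against 3 counts over that group, written as "at least". On simulated counts for 197013 windows of the TGIRT comparison of IP with input, the test recovered 84% of windows raised 4-fold, 32% of windows lowered to 0.25 of their level and 0% of windows changed 2-fold in either direction, and it called 0 unchanged windows. Only 200 windows were changed there, against 72079 called in the data. The adjusted threshold was thus stricter in the simulation, and these shares do not carry over to the data.

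A reverse transcription stop at a base was measured as the share of read ends at that base among the read ends there and on the 50 nt on its 5′ side, which stand for read-through. The base on the 5′ side of the stop is the one that would block the enzyme. Positions with at least 20 such read ends in every library of a fit and a mean stop share of at least 0.1 were tested with limma (lmFit, eBayes) on log2((stops + 1)/(read-through + 1)), with Benjamini-Hochberg adjustment at 0.05. Fits held the 6 SuperScript libraries, the 6 TGIRT libraries of untransfected cells, the 4 IP libraries of both enzymes, or the 8 overexpression and control libraries. Where both groups stop at over 99%, the ratio follows the depth. Read-through can come from fragments that end for other reasons, and positions at the start of a transcript or exon were not left out, because no hg19 annotation was used here. Simulated for the 3957 positions of the SuperScript Dimroth comparison, the test recovered 86% of positions with the odds of a stop lowered 10-fold and 14% of those lowered 3-fold, and called 5 unchanged positions. The IP libraries shared by the comparisons with input and with the Dimroth step were covered by 100 simulations of unchanged groups, each giving lists as long as the called ones by the moderated t.

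Coordinates are hg19 and count from 1. A gene table of another assembly, GRCh38.p14, was used only for the chromosomes of TRMT6 and TRMT61A, and the gene lists fixed beforehand could not be placed on hg19 and were not used. Named items follow a rule fixed beforehand: the 10 highest and 10 lowest changes per comparison among items past the threshold with every library of 1 group on the same side of every library of the other, at most 1 per 1000 nt. The rRNA, tRNA, snRNA and mitochondrial sequences were always described; regions of raised input were joined from windows above a log2 change of 5 within 20 kb of each other. Single mitochondrial windows and stop sites outside the rule, the 3-way set of mitochondrial sites, the stretch of chromosome 6 and the counts per sequence class were chosen after their values were seen. Sudden steps in the read ends of 28S, 18S and mitochondrial RNA were searched as bases with at least 2000 read ends on the 20 nt on the 3′ side, under 1% of that on the 20 nt on the 5′ side, and over 10% in the pooled inputs.

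Alternatives covered the scaling, the minimum counts, the window length, the libraries in a fit, the pseudocount, the replicate block, each replicate left out, and, added after the data were seen, DESeq2, other upstream stretches, fits without 28S rRNA and mitochondrial RNA, fits without positions that share all their counts, and untransfected libraries as comparator. A pseudocount of 4 was planned for windows and does not apply to a count test. Calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table in version 1.17.8, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.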

Results

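The series holds 20 libraries from HEK293T cells, 2 in each of 10 groups. It asks which RNAs an antibody against m1A enriches and at which bases the methyl group stops reverse transcription. The depth ranged from 4204901 to 34130189 read ends per library. With TGIRT in untransfected cells the totals were 34130189 and 28318593 for input, 19158787 and 14751475 for IP, and 17807990 and 22543920 for Dimroth-treated IP. With SuperScript they were 17959363 and 15986495, 4204901 and 5187371, and 5152359 and 6054944. Overexpression inputs held 28887641 and 22412327 read ends and overexpression IP libraries 7408471 and 8265959. Control inputs held 31006876 and 25602983 and the libraries labelled control IP 25110162 and 21261237.

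Reads on the 31 separate tRNA sequences made up 0.146 ± 0.0014% of read ends in the TGIRT IP libraries and 0.00286 ± 0.00107% in their inputs (mean ± SD, n = 2), a ratio of 51.2. Any reads placed on tRNA genes of the hg19 chromosomes, for which no annotation was used, count as nuclear here. The ratio was 11.1 with SuperScript (0.0289 ± 0.00892% against 0.00261 ± 0.000369%) and 25.9 with overexpression (0.0336 ± 0.0146% against 0.00130 ± 0.000234%). Mitochondrial read ends made up 2.49 ± 0.149% of input and 9.10 ± 0.984% of IP with TGIRT, 2.24 ± 0.172% and 12.8 ± 2.04% with SuperScript, and 3.21 ± 0.180% and 11.6 ± 0.709% with overexpression. The share of 18S rRNA was lower in IP, at 7.71 ± 4.14% against 16.5 ± 1.18% with TGIRT and 3.02 ± 0.144% against 20.9 ± 0.279% with SuperScript. The share of 28S rRNA was 43.8 ± 6.98% in SuperScript IP and 21.9 ± 0.125% in SuperScript input, while with TGIRT the difference (31.3 ± 7.37% against 24.0 ± 9.24%) was within the spread of the replicates. For tRNA and mitochondrial RNA the libraries labelled control IP went the other way. There tRNA sequences held 7.29e-05 ± 4.33e-05% of read ends against 0.000741 ± 0.000275% in control input, and the mitochondrial chromosome 3.94 ± 0.0767% against 6.03 ± 1.45%. Their share of 18S rRNA was lower than in input as well, at 12.9 ± 0.658% against 15.4 ± 0.579%. After the Dimroth step the tRNA share was 0.0257 ± 0.00763% with TGIRT and 0.00274 ± 0.00178% with SuperScript. With 2 libraries per group an exact permutation test of a single share cannot give a p below 0.333, so these shares carry no p.

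**Figure D1:**
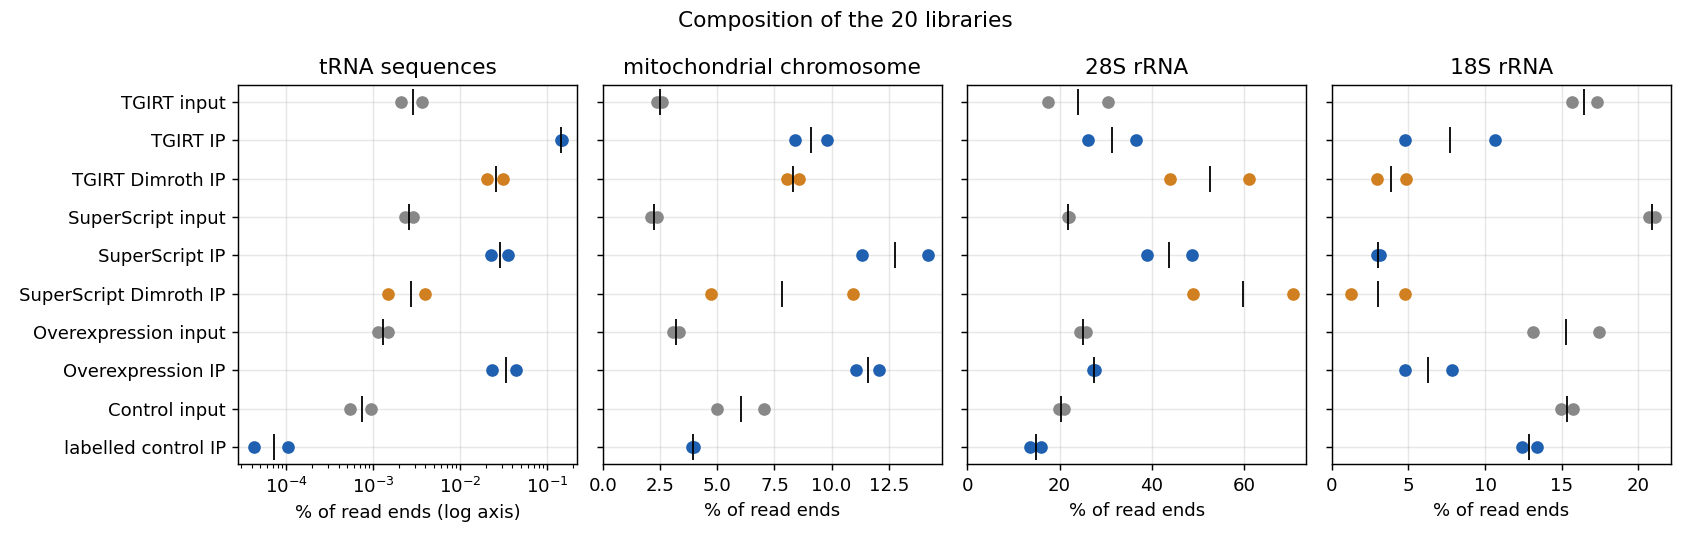
Share of read ends (x axes, percent of all read ends of a library; log axis for tRNA) on tRNA sequences, the mitochondrial chromosome, 28S rRNA and 18S rRNA in the 10 groups, with 1 point per library and a bar at the mean of 2. The tRNA share of TGIRT IP (0.146%) is 51.2 times that of its input, while the libraries labelled control IP (7.29e-05%) lie below control input (0.000741%).

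IP was compared with input for TGIRT in untransfected cells, which asks where the antibody enriches RNA when the enzyme can read through the methyl group. All 21 tRNA windows tested rose, with a median log2 change of 6.54. The ValCAC tRNA (tdbD00003264) went from 6.82 ± 6.84 to 624 ± 444 CPM (log2 change 6.54 ± 0.65 SE, edgeR adjusted p 3.3e-15). The ThrTGT tRNA (tdbD00003092) went from 2.70 ± 2.09 to 328 ± 105 CPM (6.97 ± 0.57). On the mitochondrial minus strand 108 of 138 windows rose (68 on library totals, and 55 with 5 lower by DESeq2). On the plus strand 91 of 164 rose (28 on library totals, and 29 with 26 lower by DESeq2). Positions 5701–5800 of the minus strand went from 278 ± 127 to 19855 ± 3117 CPM (6.16 ± 0.75). On the plus strand, positions 3201–3300 went from 106 ± 22.7 to 6567 ± 1820 CPM. Of the 18S rRNA windows 4 of 19 fell and 0 rose by edgeR (0 at an unadjusted p under 0.05, and 0 by DESeq2). Lower windows numbered 9 both on library totals and with DESeq2. Of 52 windows of 28S rRNA 21 rose and 2 fell (14 and 5 on library totals, 10 and 8 with DESeq2). Among snRNAs, U4atac went from 22.0 ± 14.8 to 123 ± 71.0 CPM and U1 rose as well (log2 changes 2.48 and 1.88), while U6atac fell by 2.23 on the log2 scale. With DESeq2 0 snRNA windows rose (1 at an unadjusted p under 0.05). Single nuclear windows without a read end in input rose too, such as chromosome 21 at 9654201–9654300 on the plus strand (15 ± 9.34 CPM in IP, at least 351-fold higher, edgeR adjusted p 9.4e-21). Others were chromosome 6 at 27248001–27248100 on the minus strand (6.13 ± 1.33 CPM, at least 144-fold) and chromosome 16 at 600701–600800 on the plus strand (5.82 ± 0.260 CPM, at least 137-fold). The strongest loss was at chromosome 20, 5095701–5095800, minus strand, from 3.54 ± 0.518 CPM in input to 0 (at least 27.7-fold lower). In all, 37557 of 204428 windows rose and 34522 fell in edgeR at the adjusted threshold, while without TGIRT IP replicate 1 the count was 29373. The split rests on the scaling: the median of all windows was −0.14 on TMM-scaled totals, −0.82 on library totals alone and −1.30 with DESeq2. On library totals 16535 rose and 46805 fell, and with DESeq2 16598 rose and 85629 fell. With DESeq2, 28S rRNA had a negative median (−0.35).

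IP was also compared with input for SuperScript in the same cells, which asks the same of an enzyme that the methyl group can stop. Here 15 of the 21 tRNA windows rose and 0 fell (edgeR; also 0 at an unadjusted p under 0.05, and 0 by DESeq2), with a median log2 change of 4.15. The ValCAC tRNA went from 6.54 ± 2.53 to 113 ± 25.5 CPM (4.10 ± 0.58, edgeR adjusted p 4.6e-09). GlyTCC (tdbD00000972) went from 4.52 ± 1.30 to 80.7 ± 19.5 CPM and TyrGTA (tdbD00003671) from 2.56 ± 0.0840 to 54.6 ± 33.1 CPM. Mitochondrial positions 2601–2700 of the plus strand rose from 824 ± 75.1 to 66222 ± 12006 CPM (6.33), and the adjacent 2501–2600 from 418 ± 27.9 to 57752 ± 7709 CPM (7.11). Positions 13601–13700 rose from 3.14 ± 0.660 to 95.4 ± 37.7 CPM (4.92). Of the 18S rRNA windows 16 of 19 were lower, with a median of −2.32 (19 lower on library totals and with DESeq2), and the difference between the enzymes was not tested for windows. U4atac rose from 14.3 ± 3.55 to 93.3 ± 29.9 CPM, 1 of 3 snRNA windows that rose (1 with DESeq2), and U6atac fell from 69.5 ± 1.86 to 2.56 ± 1.29 CPM. The window on chromosome 16 at 600701–600800 rose here too, from 0 to 6.58 ± 0.381 CPM (at least 85.7-fold). Chromosome 20 at 23331301–23331400, plus strand, went from 0 to 13.9 ± 1.31 CPM (at least 181-fold, edgeR adjusted p 1.1e-20). Chromosome 1 at 173835801–173835900, minus strand, fell from 21.3 ± 1.03 CPM to 0 (at least 48.4-fold lower). Of all windows, 22652 rose and 32087 fell in edgeR; 30170 were called without SuperScript IP replicate 1 and 23251 without replicate 2. The share of higher windows dropped under other scalings, with 14984 higher and 50435 lower on library totals (median of all windows −1.89 against −1.25), and 16593 and 60949 with DESeq2 (−2.01). Mitochondrial RNA as a class depends on it: 65 plus-strand windows rose and 12 fell on TMM-scaled totals, but 26 rose and 36 fell with DESeq2. On the minus strand 52 rose and 5 fell on TMM-scaled totals, but 14 and 16 with DESeq2. Likewise 28S rRNA turned from 16 higher and 11 lower to 13 and 15 on library totals and 10 and 14 with DESeq2.

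In cells that overexpressed TRMT6 and TRMT61A, the same comparison with TGIRT asks where their IP enriches RNA. Of the tRNA windows 19 of 21 rose (median log2 change 5.14) and 0 fell (edgeR; also 0 at an unadjusted p under 0.05, and 0 by DESeq2). ThrTGT (tdbD00003092) stood at 81.9 ± 31.3 CPM in IP and 1.08 ± 0.386 CPM in input (6.25 ± 0.56). On the mitochondrial chromosome 107 plus-strand and 95 minus-strand windows rose, against 38 and 46 on library totals and 52 and 44 with DESeq2 (10 and 8 lower). Positions 2601–2700 of the plus strand went from 492 ± 8.61 to 46578 ± 7720 CPM, and 13601–13700 from 13.7 ± 1.31 to 762 ± 256 CPM. Those at 5601–5700 of the minus strand went from 40.5 ± 6.50 to 3714 ± 2627 CPM. Chromosome 9 at 33658601–33658700, plus strand, rose from 0.0437 ± 0.0618 to 43.9 ± 9.27 CPM (edgeR adjusted p 2.8e-24). Chromosome 22 at 50448301–50448400, plus strand, went from 0 to 9.51 ± 0.50 CPM (at least 241-fold). U4atac rose from 3.22 ± 0.592 to 29.5 ± 9.00 CPM. The largest loss, 28S rRNA at 1201–1300 (5520 ± 8.56 to 2.10 ± 0.510 CPM, fell by 11.36 on the log2 scale), lies directly on the 5′ side of a step in the read ends. Across windows 28974 rose and 24556 fell in edgeR, with 26683 called without overexpression IP replicate 1 and 28075 without replicate 2. On other scalings 14258 rose and 50991 fell on library totals, and 17386 and 63379 with DESeq2 (medians of all windows −0.54, −1.35 and −1.51). For 28S rRNA, 16 windows rose and 5 fell on TMM-scaled totals, but 11 rose and 15 fell on library totals and 10 and 15 with DESeq2.

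The libraries labelled control IP lacked this enrichment relative to control input. Not one of the 21 tRNA windows rose and 9 fell (edgeR; 0 higher and 14 lower at an unadjusted p under 0.05, 0 and 8 by DESeq2, 0 and 3 on library totals). The ArgACG tRNA (tdbD00002599) went from 0.725 ± 0.181 to 0.0278 ± 0.0393 CPM (−4.34 ± 0.71, edgeR adjusted p 1.4e-05). The ValCAC tRNA dropped from 0.285 ± 0.0010 CPM to 0 (at least 9.20-fold lower), a call that ended when windows needed a mean count of 20. Of mitochondrial windows 88 on the plus strand and 61 on the minus strand fell and 0 rose (edgeR; 0 also at an unadjusted p under 0.05, and 0 by DESeq2), against 9 and 3 lower on library totals. Among them were positions 12201–12300 of the plus strand, from 14.7 ± 6.26 to 1.01 ± 0.769 CPM. Among the gains, chromosome 20 at 21483601–21483700 on the minus strand reached 0.209 ± 0.0970 CPM from 0 (at least 5.87-fold), and its call ended without either control input replicate. In all 3239 windows rose and 4976 fell in edgeR, against 294 and 167 on library totals and 2529 and 4817 with DESeq2, and the median of all windows was 0.03, 0.51 and −0.01. The count rested on single libraries: 15558 without control IP replicate 1, 4792 without control IP replicate 2, 2125 without control input replicate 1 and 3084 without control input replicate 2.

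**Figure D2:**
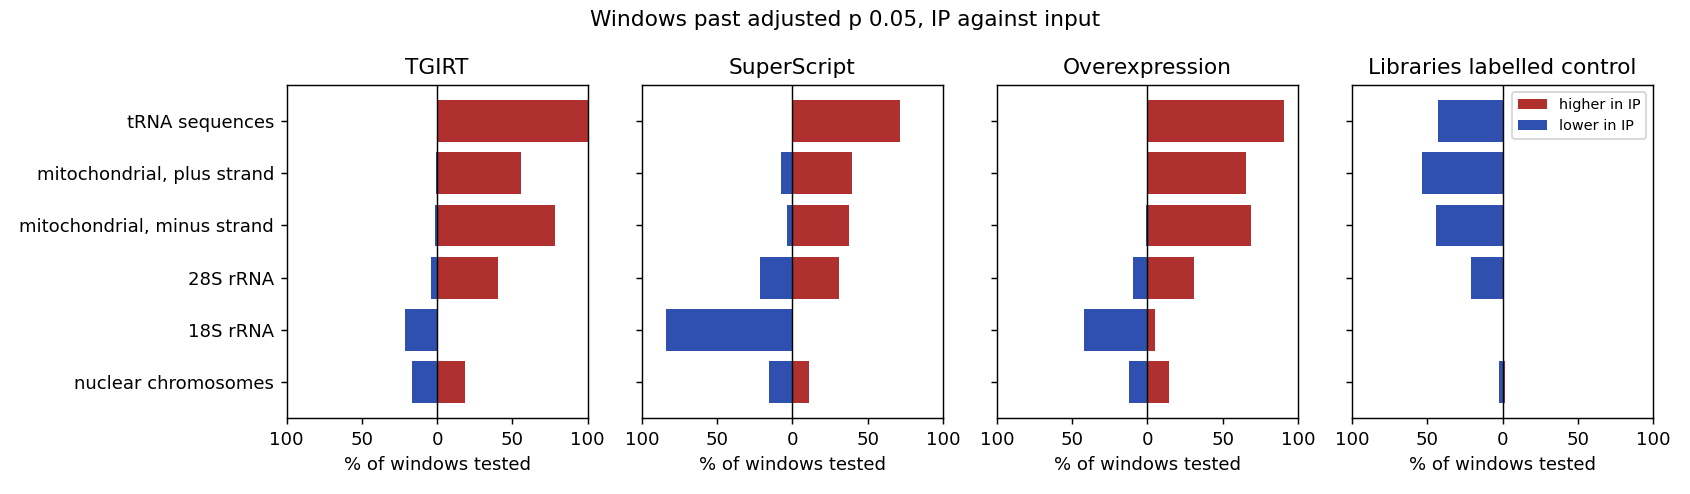
Percent of the windows tested that were higher (red) or lower (blue) in IP than in input (x axes) for each sequence class (y axis), in the comparisons with TGIRT, SuperScript, overexpression and the libraries labelled control IP, by edgeR on TMM-scaled totals with 2 libraries per group. All 21 tRNA windows rose with TGIRT and 9 fell in the libraries labelled control IP; with DESeq2 scaling these classes turn to more lower than higher windows: mitochondrial RNA with SuperScript (26 higher and 36 lower on the plus strand, 14 and 16 on the minus strand), 28S rRNA with SuperScript (10 and 14) and overexpression (10 and 15), and nuclear windows with TGIRT (16483 and 85576) and overexpression (17262 and 63328), while on library totals alone 28S rRNA with SuperScript (13 and 15) and overexpression (11 and 15) and nuclear windows with TGIRT (16403 and 46782) and overexpression (14142 and 50947) do so, and nuclear windows of the control comparison turn the other way (294 and 149).

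The difference between the overexpression and control IP enrichments was tested as an interaction, which asks whether more methyltransferase changes what the antibody binds. In 17 of 21 tRNA windows the enrichment was higher with overexpression, with a median log2 difference of 8.0, and 0 were lower (edgeR, also 0 at an unadjusted p under 0.05, and 0 by DESeq2). The libraries labelled control IP held only 26 and 9 read ends on all tRNA sequences. This median is thus fitted near the count floor and is not a measured size. The ArgACG tRNA stood at 24.0 ± 8.41 CPM in overexpression IP and 0.0278 ± 0.0393 CPM in the libraries labelled control IP (difference 9.57 ± 0.82, edgeR adjusted p 1.7e-17). Mitochondrial positions 5601–5700 of the minus strand stood at 3714 ± 2627 against 3.73 ± 3.45 CPM (9.55 ± 0.93). Higher enrichment was called in 136 plus-strand and 121 minus-strand mitochondrial windows, against 60 and 48 on library totals and 103 and 62 with DESeq2. It was also called for U4atac, U4 and U12 (5.92, 4.19 and 3.36). Chromosome 1 at 161369501–161369600, minus strand, held 451 ± 74.4 CPM in overexpression IP and 0.0117 ± 0.0165 CPM in the libraries labelled control IP, with inputs at 3.06 ± 0.270 and 0.381 ± 0.0127 CPM. The whole difference depends on the comparator: against the untransfected TGIRT libraries 634 windows were called (328 higher, 306 lower) in place of 35812 (20592 and 15220). No tRNA window was among the 634 (0 called by edgeR, 2 lower and 0 higher at an unadjusted p under 0.05), and no plus-strand mitochondrial window was (0, and 2 lower at an unadjusted p under 0.05). The ValCAC difference turned from 11.71 to −0.52, where the first is a fitted value, as the libraries labelled control IP held no read end there. The mitochondrial minus strand turned from 121 higher and 0 lower to 0 and 2, and 28S rRNA from 22 and 2 to 0 and 3. Without overexpression IP replicate 1 the count was 18810 and without replicate 2 19539. On library totals 5163 windows were higher and 49883 lower, and with DESeq2 11564 and 41731, with medians of all windows at −0.56 (TMM), −1.85 and −1.49. The only called 18S rRNA window was higher on TMM-scaled totals, against 1 higher and 8 lower on library totals and 0 and 1 with DESeq2.

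Overexpression and control inputs were compared to see what the transfection changed in the RNA before IP. The raised windows of the chromosome 20 stretch 5918501–5931200, on the chromosome of TRMT6, together rose from 5.54 ± 1.76 to 2397 ± 226 CPM. Those of the chromosome 14 stretch 103995501–104001400, on the chromosome of TRMT61A, rose from 16.6 ± 0.448 to 3542 ± 208 CPM. The median log2 change was 8.78 over the 34 windows on chromosome 20, 33 of them on the minus strand, and 7.88 over 25 windows, 15 of them on the plus strand. A pair of stretches on chromosome 17 rose as well, 61957601–61957700 from 0 to 21.7 ± 2.68 CPM (at least 610-fold, edgeR adjusted p 9.1e-26) and 61994001–61994700 from 0.0520 ± 0.0735 to 126 ± 22.0 CPM. So did 10 windows within chromosome 6 at 74229901–74231100 (together 0.534 ± 0.204 to 59.9 ± 1.40 CPM). Over all of that stretch the minus strand held 3541 and 4039 read ends in control inputs and 5664 and 4896 in overexpression inputs. Raised as well were chromosome 7 at 5570301–5570800 (0.0109 ± 0.0155 to 11.5 ± 0.531 CPM) and 4 windows on chromosome 19 at 55627301–55627800. With DESeq2 the 61957601–61957700 window was no longer called. Under the same rule 8 further stretches rose, 3 on chromosome 1 and 1 each on chromosomes 4, 6, 12, 15 and X. Control inputs held no read end in them except at chromosome 1, 932501–934000, so their median log2 changes (5.07 to 6.44) are fitted values and not measured sizes. A window on chromosome 9 fell from 0.196 ± 0.0910 CPM to 0 (fitted log2 change −5.14). The raised ones reached at most 2.75 CPM in overexpression input, and libraries without overexpression held read ends in all of them. Mitochondrial RNA fell, in 117 of 164 plus-strand windows (median −1.73; 7 on library totals) and 20 of 138 minus-strand windows (0 called by edgeR on library totals, 18 at an unadjusted p under 0.05; 6 by DESeq2). Positions 5401–5500 of the plus strand went from 32.4 ± 22.6 to 3.69 ± 0.153 CPM (−3.13 ± 0.42). None rose (0 by edgeR, 0 at an unadjusted p under 0.05, and 0 by DESeq2). U12, U4, U4atac and U5 rose by 1.77, 2.02, 1.56 and 1.78 on the log2 scale, and the ThrTGT tRNAs tdbD00003091 and tdbD00003092 by 2.65 and 1.73. On library totals 0 snRNA and 0 tRNA windows were called by edgeR (5 and 3 at an unadjusted p under 0.05), and with DESeq2 1 of each. In mean share of read ends, overexpression input lay between control input and untransfected TGIRT input for all of these classes. The mitochondrial share was 6.03% in control, 3.21% in overexpression and 2.49% in untransfected input. For snRNA it was 0.0162, 0.0390 and 0.102%, and for tRNA 0.000741, 0.00130 and 0.00286%. These changes may thus lie in the control libraries, and the inputs were not tested against untransfected ones. In edgeR 6919 windows rose and 4751 fell; on library totals 176 and 30, and with DESeq2 7728 and 2807. Counts without 1 library were 1016 and 1726 (overexpression input replicates 1 and 2) and 3214 and 722 (control input replicates 1 and 2).

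**Figure D3:**
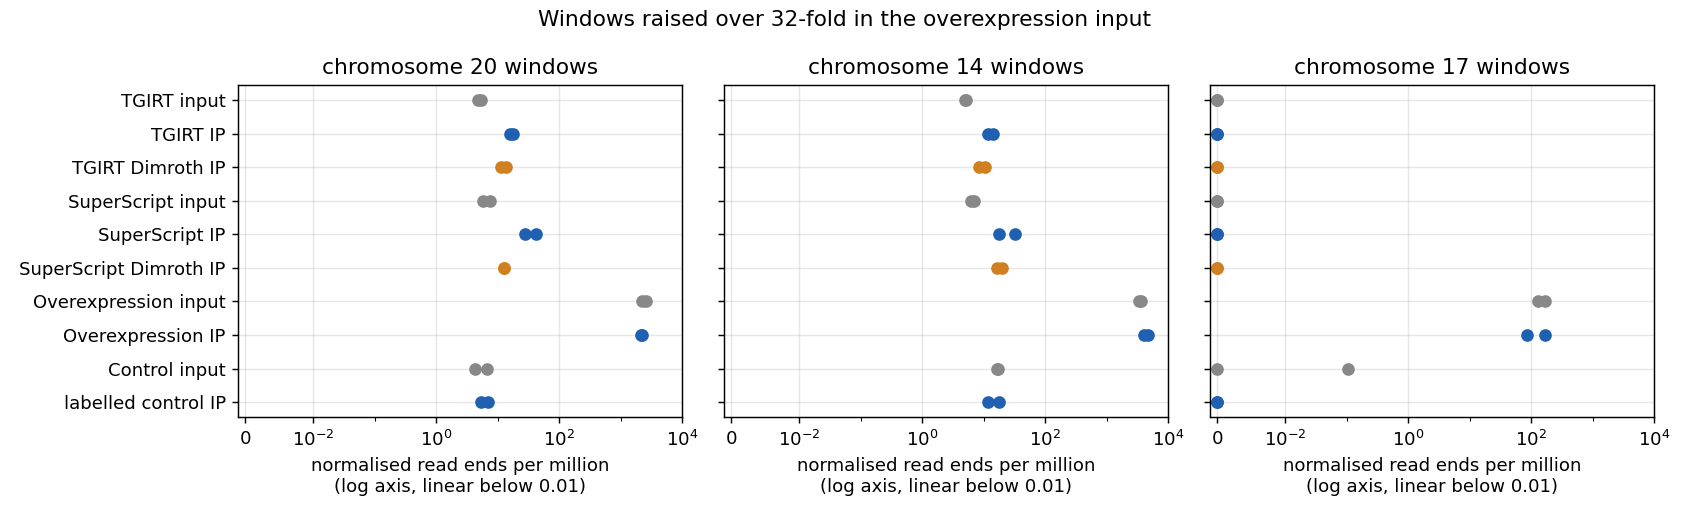
Normalised read ends (CPM; x axes, log scale, linear below 0.01) over the windows raised over 32-fold in the overexpression input on chromosomes 20, 14 and 17, with 1 point per library in each of the 10 groups. Overexpression inputs average 2397 CPM on chromosome 20 and 3542 CPM on chromosome 14, and control inputs 5.54 and 16.6 CPM.

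Stops with SuperScript were compared between IP and input, which asks at which bases antibody-selected RNA blocks the enzyme. On the mitochondrial plus strand 21 of 77 positions rose and 1 fell. At position 2835 the stop share went from 5.63 ± 0.52% to 73.1 ± 0.71% (log2 change of the stop to read-through ratio 5.50 ± 0.32, limma adjusted p 0.0032). It went at 6271 from 2.10 ± 0.044% to 43.0 ± 5.2%, at 7884 from 2.01 ± 0.80% to 40.9 ± 0.22% and at 1280 from 2.14 ± 0.11% to 31.2 ± 1.5%. Positions on nuclear chromosomes rose too, such as chromosome 11 at 10529947, minus strand, from 7.86 ± 3.03% to 86.3 ± 4.44%. Whether such positions hold reads of mitochondrial RNA placed on a nuclear copy was not checked. The stop at base 76 of 5.8S rRNA fell from 59.1 ± 19.0% to 6.56 ± 0.866%, and chromosome 17 at 29877165, plus strand, from 48.3 ± 13.4% to 0. Over all 3957 positions 171 rose and 107 fell in limma. In 4 of these calls both groups stopped at over 99%, where the ratio follows the depth and not a change of the stop. The calls depend on the libraries in the fit: the compared groups alone gave 883. Leaving out any SuperScript IP or input replicate left 0 called by limma, with 719 and 704 (IP replicates 1 and 2) and 642 and 686 (input replicates 1 and 2) at an unadjusted p under 0.05, against 1060 with all.

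The Dimroth comparison with SuperScript asks which of these stops go away when m1A is turned into N6-methyladenosine. On the mitochondrial plus strand 17 of 77 positions fell and 1 rose; position 2835 dropped from 73.1 ± 0.71% to 11.5 ± 0.61% (−4.38 ± 0.32, limma adjusted p 0.0072). Of the 21 mitochondrial positions that rose in IP, 13 fell with the Dimroth step. Both lists use the same IP libraries; independent lists of their size would share 4.64 positions. In 100 simulations of unchanged groups with shared IP libraries, lists of the same lengths shared 8.63 positions on average and up to 13. Over all 3957 positions 43 were shared, against 46.9 on average and up to 58 in the simulations. Chromosome 17 at 39845241, plus strand, fell from 36.3 ± 3.68% to 2.13 ± 1.01%. Other stops rose, at base 1641 of 18S rRNA from 1.53 ± 0.19% to 34.9 ± 1.7% and at base 4068 of 28S rRNA from 3.64 ± 0.40% to 47.4 ± 0.73%. Neither was among the calls of the Dimroth comparison with TGIRT. In all 96 positions rose and 166 fell in limma, with both groups at over 99% in 16 of these calls. These calls depend on the libraries in the fit: the compared groups alone gave 0 by limma. The 20 positions picked by the naming rule missed the threshold there. Their log2 changes are differences of the same group means in both fits, so their direction could not change. A replicate block lowered the count of calls as well. Without SuperScript IP replicate 1 or 2 there were 0 calls (645 and 621 at an unadjusted p under 0.05), without Dimroth replicate 1 there were 126 and without Dimroth replicate 2 625.

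SuperScript and TGIRT were compared in IP to see which stops depend on the enzyme. Of 130 mitochondrial plus-strand positions 33 stopped SuperScript more and 11 stopped TGIRT more; position 2835 stood at 73.1 ± 0.71% against 24.6 ± 3.6%. Chromosome 5 at 180618701, minus strand, had a stop share of 95.9 ± 1.22% with SuperScript and 3.28 ± 0.230% with TGIRT (9.23 ± 0.38, limma adjusted p 0.0064), and chromosome 16 at 22308488, plus strand, 32.9 ± 3.26% and 0.309%. TGIRT stopped more at chromosome 17, 8029063, plus strand (86.0 ± 2.85% against 0), and at mitochondrial position 8366 (92.8 ± 1.2% against 6.02 ± 4.0%), where TGIRT input stopped at 94.4 ± 2.4% as well. Of 15331 positions 1096 were higher and 1181 lower with SuperScript in limma, 115 of them with the counts of another position and 14 with both groups at over 99%; without TGIRT IP replicate 1 or 2 there were 0 calls (3015 and 3142 at an unadjusted p under 0.05, 5124 with all).

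**Figure D4:**
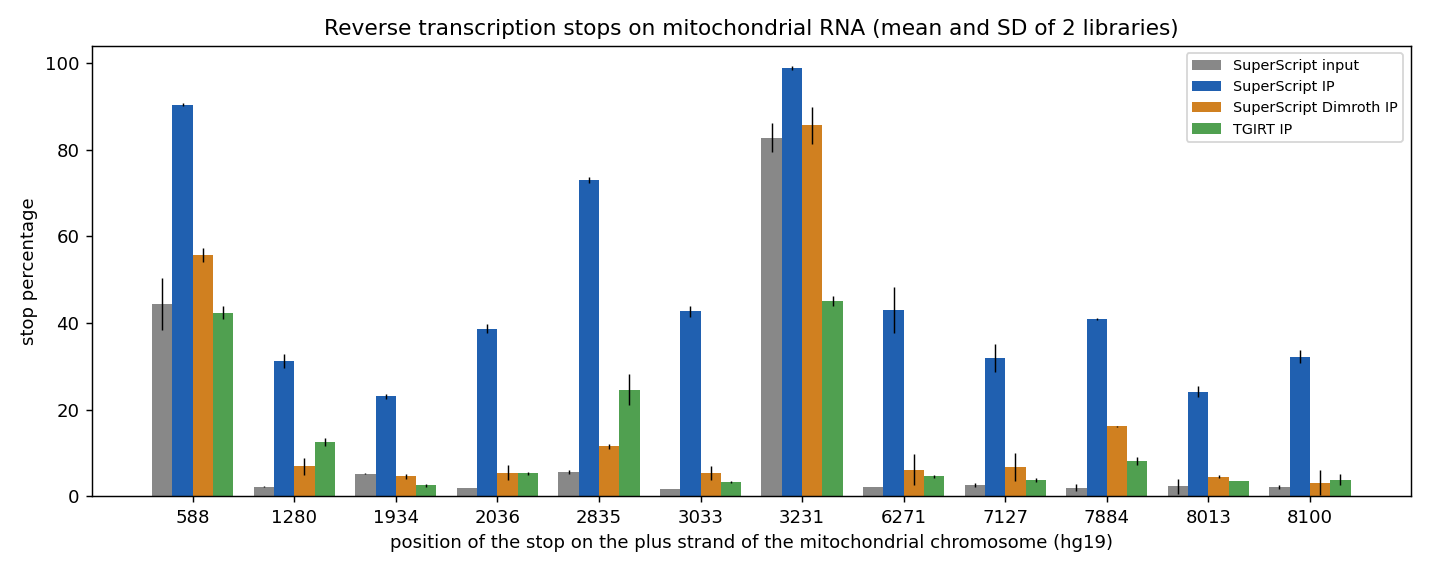
Stop share (y axis, percent of read ends at the base among those there and on the 50 nt on its 5′ side) at the 12 mitochondrial plus-strand positions (x axis, hg19) that rose in SuperScript IP, fell with the Dimroth step and exceeded TGIRT IP, a set chosen after the values were seen from comparisons that share the SuperScript IP libraries, as mean and SD of 2 libraries. Position 2835 reads 5.63% in SuperScript input, 73.1% in IP, 11.5% after the Dimroth step and 24.6% in TGIRT IP; 588 and 3231, which lie within 20 nt of steps, also stopped SuperScript in input, at 44.4% and 82.8%.

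With TGIRT the Dimroth step lowered 445 of 9254 stops and raised 263 (limma). In 24 of these calls both groups stopped at over 99%, all 5 lower calls on tRNA sequences among them, so these calls show no change of a stop. The stop at chromosome 6, 62284123, plus strand, fell from 49.0 ± 3.86% to 2.25 ± 0.115% (−5.38 ± 0.33, limma adjusted p 0.005), a call that ended with 25 nt of read-through. Chromosome 11 at 10529738, minus strand, went from 32.7 ± 1.55% to 1.02%. It was not checked whether reads of mitochondrial RNA were placed at these nuclear positions. Chromosome 5 at 178311737, plus strand, rose from 2.64% to 68.5 ± 5.14%. Chromosome 6 at 13214303, plus strand, rose with both enzymes, from 5.50 ± 1.43% to 67.7 ± 3.52% with TGIRT and from 4.86% to 74.9 ± 27.9% with SuperScript, the latter not called without either IP replicate. On the mitochondrial plus strand 13 of 150 positions fell and 2 rose; the rise at 578 and the losses at 2554 and 2564 lie within 20 nt of steps. The comparisons of both enzymes share no library. Of the 166 positions lowered with SuperScript 96 were measured with TGIRT and 89 of them were lower, 35 of them called (5.55 expected by chance; 31 called without positions at over 99% in both groups). Of the 96 raised 68 were measured, 62 were higher and 28 called (1.91 by chance). The TGIRT count itself was 125 and 34 without IP replicates 1 and 2, and 2 and 62 without Dimroth replicates 1 and 2.

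The stops of overexpression IP were compared with those of the libraries labelled control IP with TGIRT. Mitochondrial position 3228 stood at 80.7 ± 0.89% against 1.58 ± 0.59% (7.64 ± 0.88, limma adjusted p 0.0068), position 579 at 93.2 ± 3.3% against 14.6 ± 5.7% and position 1603 at 73.5 ± 2.2% against 2.99 ± 1.5%. Against untransfected TGIRT IP none of the 3 was called, and 3228 turned to −0.71, with untransfected TGIRT IP at 85.0 ± 12%. All 3 lie within 20 nt of steps in IP libraries. Chromosome 1 at 20987863, minus strand, fell to 2.72 ± 1.15% from 52.3 ± 7.55%, and chromosome 14 at 103995536, plus strand, inside the stretch raised in the overexpression input, to 1.68 ± 0.161% from 30.3 ± 2.1%. Of 11661 positions 893 were higher and 761 lower in limma, with both groups at over 99% in 6 of these calls. Counts fell without 1 library, to 605 and 830 without overexpression IP replicates 1 and 2 and to 474 and 281 without control IP replicates 1 and 2.

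Read ends on 28S rRNA, 18S rRNA and the mitochondrial plus strand stepped up at single bases in some libraries. The deepest on the mitochondrial chromosome lay at 2546 and 2553 in TGIRT IP (replicates 1 and 2) and at 2587 and 2580 in overexpression IP. The other mitochondrial steps lay at 578 to 579, 1585 to 1589 and 3212 to 3231, in 3, 5 and 7 libraries and in 0 input libraries. In the pooled inputs the 20 nt on the 5′ side held 10.4% to 29.3% of those on the 3′ side at these steps, so inputs dropped there too. The search asks for over 10% in the pooled inputs, so the 0 does not mark these steps as particular to IP. At these places the replicates of a group lay 0 to 2 nt apart, and the 100 nt past a step held as few as 2262 read ends (position 3231 in SuperScript IP). In SuperScript and overexpression IP the first steps on 28S rRNA lay at base 1303 (both SuperScript replicates) and at 1309 and 1303. Further 28S steps lay between bases 111 and 1956, each in 1 or 2 libraries, at 4419 in TGIRT input replicate 2, and at 4680 in all 6 TGIRT libraries of untransfected cells, input included. In overexpression IP replicate 2 the 20 nt past mitochondrial position 2580 held 201094 read ends and the 20 nt before it 0. On 18S rRNA lay 12 steps, 11 of them in input libraries, such as 1377 and 1373 and also 1478 and 1484 in overexpression input. With 21 steps on 28S rRNA and 19 on the mitochondrial chromosome they make 52 in 16 of the 20 libraries. The steps of TGIRT and overexpression IP at 2546 to 2587 lie inside the window at mitochondrial positions 2501–2600, where SuperScript IP had none. Those at 28S bases 1303 and 1309 lie just past the window at bases 1201–1300.

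**Figure D5:**
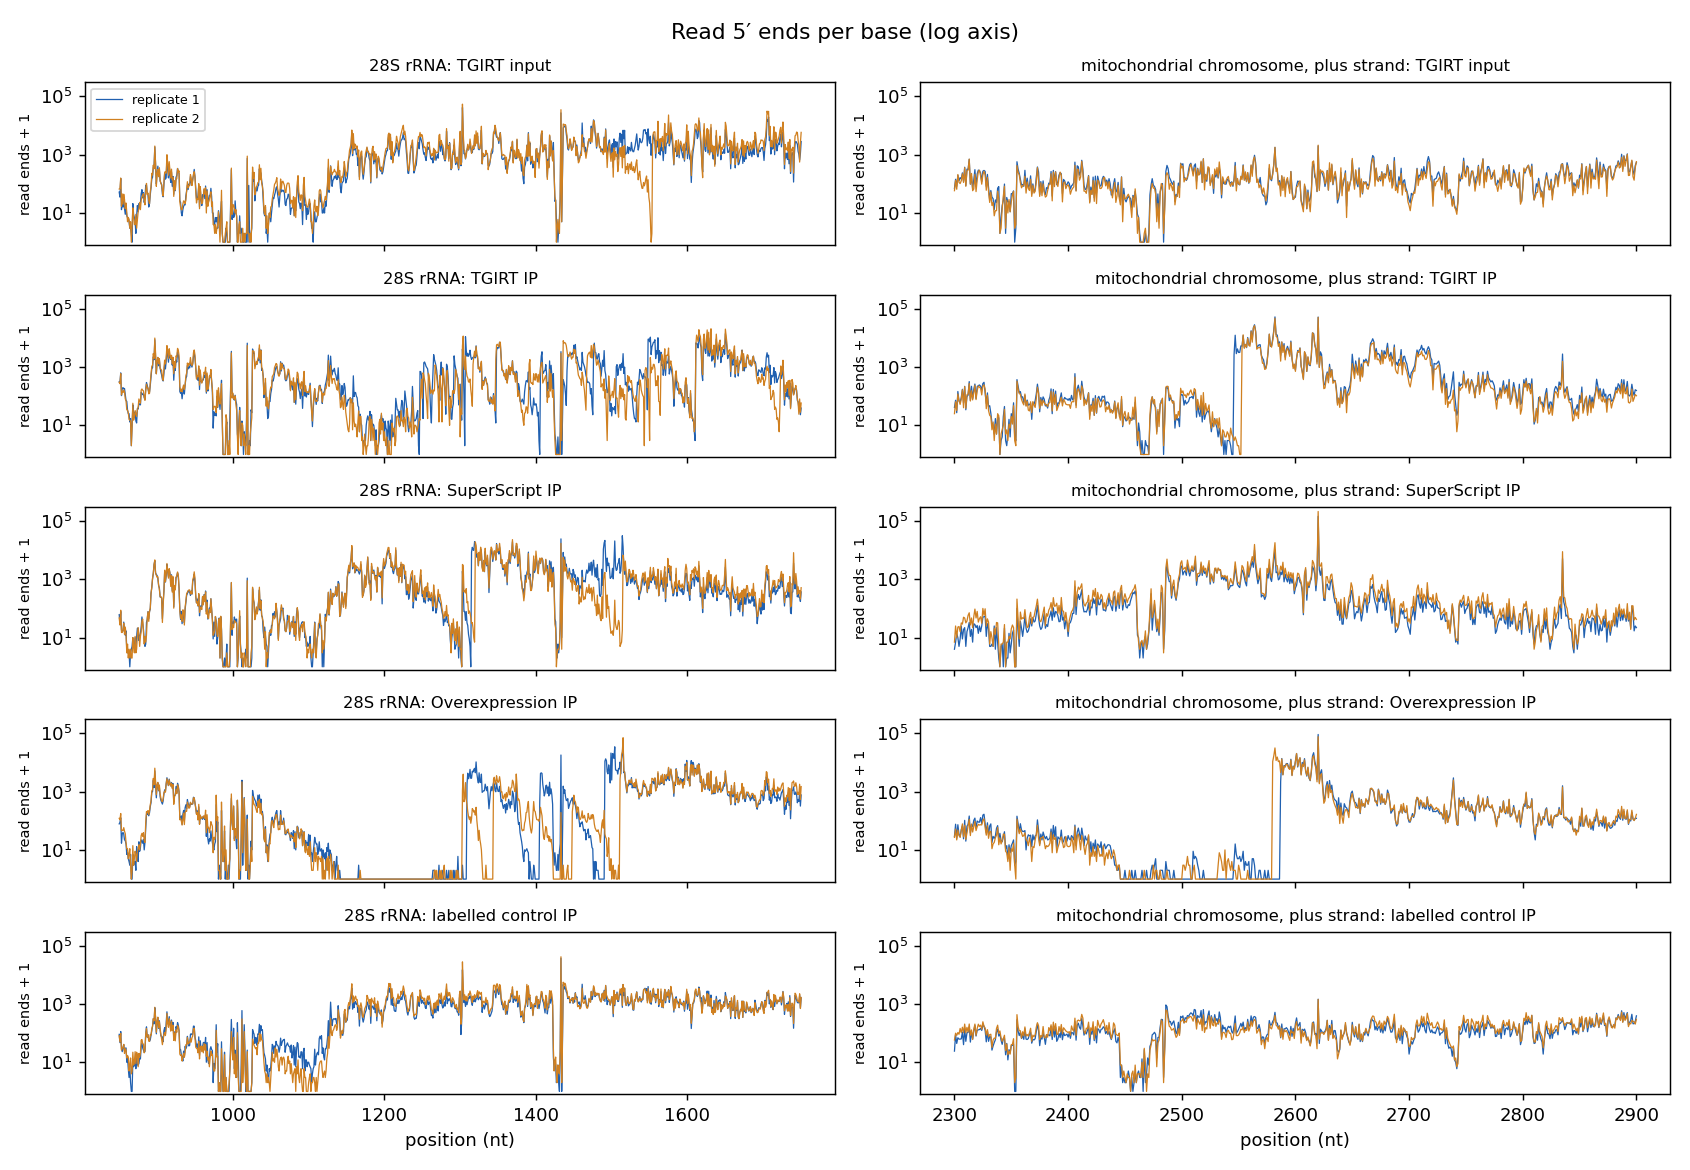
Read 5′ ends per base plus 1 (y axes, log scale) along 28S rRNA (left) and the mitochondrial plus strand (right; x axes, position in nt) for TGIRT input, TGIRT IP, SuperScript IP, overexpression IP and the libraries labelled control IP, with 1 line per replicate. On the mitochondrial stretch shown, read ends step up at 2587 and 2580 in overexpression IP and at 2546 and 2553 in TGIRT IP.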

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

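Of the tests of explanations in this part, only that of plasmid reads was written before its result was seen. All others, and the division of the step tests by place and group, were chosen after.

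The IP enrichment differed between overexpressing and control cells in a test of the difference itself (an interaction in edgeR). It was called in 35812 windows, in 17 of the 21 tRNA windows and in 136 of the 164 plus-strand mitochondrial windows. Against untransfected TGIRT libraries in place of the control libraries, the counts were 634, 0 and 0 (edgeR; 0 higher and 2 lower at an unadjusted p under 0.05 in each of the last 2 classes). The difference thus rests on the control libraries.

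These libraries lack the enrichment seen in the other IP libraries. A lower depth argues the wrong way, since they hold 2.96 times the read ends of the overexpression IP libraries. Overexpression as the cause of the enrichment is argued against by untransfected cells, whose tRNA windows rose by a median of 6.54 on the log2 scale with TGIRT. Over the 23374 windows that rose over 2-fold in both other TGIRT comparisons, the control comparison had a median of 0.15 (quartiles −0.35 to 0.68), and the control IP profile correlated with control input across windows at 0.90 and with overexpression IP at 0.33, as input RNA under an IP label would give. The same RNA as control input would not lower tRNA windows (median −3.20, 9 of 21 called) or snRNA windows (−2.22, 6 of 8). Nor would it lower 88 plus-strand and 61 minus-strand mitochondrial windows. On library totals these were 3 tRNA, 1 snRNA, 9 and 3 mitochondrial windows. The −3.20 is fitted near the count floor. All tRNA sequences together held 26 and 9 read ends in the libraries labelled control IP and 290 and 140 in control input. Mislabelled input RNA thus stays open, as do an IP that failed to bind and a biological loss of m1A in control cells, which were not tested.

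Read ends step up at single bases of 28S rRNA, 18S rRNA and mitochondrial RNA in some libraries. A ceiling on local depth in the processing, set by the next 100 nt, would need every library with a step to be deeper there than every library without. At each of the other mitochondrial steps (578 to 579, 1585 to 1589 and 3212 to 3231) at least 7 libraries without a step were deeper, which argues against such a ceiling there. At the first 28S steps of overexpression IP 14 were deeper. This does not exclude a ceiling reached further downstream, since the 100 nt past bases 1491 and 1511 held 460006 and 379355 read ends (replicates 1 and 2). At the first 28S steps of SuperScript IP and at the deepest mitochondrial steps (2546 to 2587) 0 libraries were deeper, which leaves a ceiling open at these places. Antibody selection around 1 modified base was taken to put replicates at the same base. The median distance was 7 nt at the deepest mitochondrial steps (7 nt in both TGIRT IP and overexpression IP). It was 3 nt at the first 28S steps of SuperScript and overexpression IP (0 and 6 nt) and 0.5 nt at the other mitochondrial steps. Selected fragments can end at several bases around a modified one, and a fixed end of the RNA would also put replicates at the same base. These distances therefore do not decide on antibody selection. At the other mitochondrial steps the pooled inputs dropped too, with 10.4% to 29.3% on the 5′ side. Of all steps 14 lie in input libraries (11 on 18S rRNA, and 28S bases 4419 and 4680). This argues against antibody selection at the 18S and last 28S steps. On 18S rRNA deeper libraries without a step were found at 4 of 5 places (3, 4, 6 and 1 libraries), and 0 at the last. This argues against a ceiling set by the next 100 nt at those 4 places, most weakly where only 1 library was deeper. Such a ceiling stays open at the last 18S place, and a ceiling reached further downstream is not excluded at any of them. At the further 28S places 0 to 9 libraries were deeper.

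Stretches of chromosomes 17, 6, 7 and 19, and 8 smaller ones, rose in the overexpression input although TRMT6 and TRMT61A lie on chromosomes 20 and 14. The test written beforehand asked whether at least 10% of the reads on chromosome 17 lie on the minor strand; the lower of the 2 inputs held 10.4% and the other 11.9%, with both stretches pooled after the values of each were seen (0% in both inputs at 61957601–61957700, and 12.2% and 14.1% at 61994001–61994700). The stretches of the transfected genes, which the plasmids carry, held 0.611% and 0.405% (chromosome 20) and 0.611% and 0.580% (chromosome 14). A share of 10% thus does not mark plasmid reads, and the test decides nothing. In read ends the minor strand of the chromosome 14 stretch did rise, to 951 and 648 from 0 and 2 in control inputs. The share was 2.01% and 1.31% on chromosome 6 (where control inputs also hold many read ends), 10.8% and 9.98% on chromosome 7, 36.2% and 49.0% on chromosome 19 and 0 to 0.114% in 8 smaller raised stretches. On chromosome 17 all libraries without overexpression together held 0 read ends at 61957601–61957700 and 4 at 61994001–61994700. Plasmid reads would give this, and so would RNA that the cells make only after transfection. Plasmid reads and a change of the cells' own RNA both stay open.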

How the results depend on the processing

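Among 220 named windows and stop sites, 2578 values were recomputed under alternatives. Of those that leave out 1 library, 668 kept direction and side of the threshold, 223 kept direction but missed the threshold and 0 reversed. The naming rule asks for separated libraries, so leaving out 1 cannot reverse a stop and makes a reversal of a window less likely. The 0 is thus no support. Among the other values the counts were 1576, 107 and 4, in the same order. For stops, fits that change only the positions tested, the libraries outside the compared groups or the replicate block leave the value as it was. The reversals came with untransfected libraries as comparator, added after the data were seen: chromosome 6 at 27248001–27248100 (−1.04) and the ValCAC tRNA (−0.52) in the overexpression effect, and the overexpression stops at mitochondrial position 3228 (−0.71) and chromosome 19, 49993873 (−0.66). The −1.04 is a fitted value and not a measured size, since TGIRT input held no read end in that window. The cause was not tested for any change below, except where fewer items were tested.

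Outside the nuclear chromosomes, higher minus lower windows reversed with DESeq2 for SuperScript on the mitochondrial plus strand (−10), minus strand (−2) and 28S rRNA (−4), for overexpression on 28S rRNA (−5) and for the overexpression effect on 18S rRNA (−1). On library totals alone they did so for 28S rRNA with SuperScript (−2) and overexpression (−4) and for the overexpression effect on 18S rRNA (−7), and with untransfected libraries for that effect on the mitochondrial minus strand (−2) and 28S rRNA (−3). Nuclear windows reversed with DESeq2 and on library totals for TGIRT (−69093 and −30379), overexpression (−46066 and −36805) and the overexpression effect (−30362 and −44847), and on library totals for control (145).

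Window counts moved over 1.5 times as follows, in the order TGIRT, SuperScript, overexpression, control, overexpression effect and input where all 6 moved. With a mean count of 20, which tests fewer windows, they were 27604, 27351, 26037, 5241, 20191 and 6052. On library totals control had 461, the overexpression effect 55046 and input 206; with a mean count above 1, control had 5247 and input 6120; with the compared groups alone, control had 1018 and input 43704. DESeq2 gave 80765 for overexpression, and untransfected libraries 634 for the overexpression effect. Leaving out 1 library gave 29373 to 61200 (TGIRT), 23251 to 44340 (SuperScript), 26683 to 41825 (overexpression), 2125 to 15558 (control), 18810 to 38234 (effect) and 722 to 3214 (input), the lone library being assumed to vary like the other groups.

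For stops, a depth of 10 gave 77 (SuperScript Dimroth), 35 (SuperScript IP against input), 1191 (SuperScript against TGIRT) and 119 (TGIRT Dimroth). A pseudocount of 5 gave 513, 735 and 2754 (SuperScript Dimroth, SuperScript IP against input, overexpression), and a stop share of 0.2 gave 1025 for overexpression. The compared groups alone gave 0 for SuperScript Dimroth (limma; 978 at an unadjusted p under 0.05), 883 for SuperScript IP against input, 329 for TGIRT Dimroth and 406 for overexpression. Leaving out 1 library gave 0 to 625, 0 to 0 (642 to 719 at an unadjusted p under 0.05), 0 to 2453, 2 to 125 and 281 to 830 (SuperScript Dimroth, SuperScript IP against input, SuperScript against TGIRT, TGIRT Dimroth, overexpression; limma).

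A replicate block gave 107, 159 and 259 for SuperScript Dimroth, SuperScript IP against input and TGIRT Dimroth, and counts within 1.5 times elsewhere (71934 for TGIRT windows). The titles give the same replicate number to an input and an IP library of each kind. Input and IP residuals correlated at 0.56 for TGIRT and control, −0.01 for SuperScript and 0.09 for overexpression. Those of TGIRT Dimroth IP correlated at −0.57 with TGIRT IP and −0.62 with TGIRT input. The main fits leave out any such pairing, and a replicate block common to all groups does not model pairs that differ between groups. A pseudocount of 4 for windows was not run. The shallowest library, a SuperScript IP library, held 4204901 read ends.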

Other observations

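All tests in this part were chosen after the values were partly seen.

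The strand opposite to 28S rRNA held few read ends, with 0.00161 ± 0.000574% in IP and 0.000214 ± 4.13e-05% in input with TGIRT, and 0.0106 ± 0.00174% and 0.000254 ± 0.00014% with overexpression (mean ± SD, n = 2, no test). With SuperScript (0.00275 ± 0.00271% and 0.000167 ± 0.000129%) the difference was within the spread of the replicates. The libraries labelled control IP held 0.000366 ± 0.000105% and control input 0.000872 ± 0.000209%. Among the snRNAs, U2 at bases 101–200 fell in all 4 comparisons of IP with input, by −1.45, −4.09, −3.79 and −3.87 on the log2 scale (TGIRT, SuperScript, overexpression, control), and U6atac did too (−2.23, −4.78, −2.91 and −2.40). U4atac parted from them, with 2.48, 2.71 and 3.20 in the first 3 and −2.72 in the control comparison.

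On chromosome 6 between 26 and 29 Mb, 41.8% of 622 windows rose in IP with TGIRT against 18.3% of all nuclear windows, 33.0% against 11% with SuperScript and 38.1% against 14.1% with overexpression. In the control comparison 0.322% rose there against 1.59%. In the comparison of the inputs 9.97% rose there against 3.39%. The stretch was picked for its share of higher windows, so these values do not test whether it differs from the rest.

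Stops that the Dimroth step lowered with SuperScript were mostly lower with TGIRT, in libraries that the 2 comparisons do not share: 92.7% of 96 positions, against 57.6% of 2259 positions not called with SuperScript. Among stops that rose, 91.2% of 68 were higher with TGIRT against 42.4%. Without positions at over 99% in both groups the shares were 92.0% and 91.0%. The 92.7% may reflect a chemical change of the RNA that both enzymes read. A shift of read-through by the alkaline treatment itself was not tested.

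Names that look like synthetic sequences held few reads: oneUV2 had 10 and 2 in the libraries labelled control IP, 8 in overexpression IP replicate 2 and 1 in control input replicate 2, and the other such names at most 2 per library.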
